A study of Mus musculus with 6 samples.

How the data were processed

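Total RNA of sorted c-Kit+ leukemic spleen cells in 6 samples was measured on Affymetrix arrays, 3 for Mx1-Cre Cbfb+/56M and 3 for Chd7f/f Mx1-Cre Cbfb+/56M. The series' design text names a mouse Gene 2.0 ST array and calls the samples of a genotype independent. The labels' protocol for labelling names a human array of the same generation, and the deposited probe sets carry mouse genes. The design text does not say in so many words that each sample is 1 mouse, so p-values measure the spread between these samples.

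The authors deposited 1 value per probe set and array on the log2 scale. Affymetrix Expression Console and RMA are named in the submitters' processing notes; their versions and settings are not given in the sources used here. RMA corrects background, equalises the distributions of arrays and summarises probes on the log2 scale, and differences between arrays in total signal are no longer visible after it. The table holds 41345 probe sets with 0 missing values, between 1.78 and 13.5. Medians of the 6 arrays were 4.84, 4.79 and 4.72 for the control and 4.82, 4.72 and 4.77 for Chd7f/f. The log base rests on the method named and on this range, and values were not centred per gene. Detection calls per probe set are not analysed here, so low levels may lie near background, and the number of arrays limits the precision.

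Probe sets were named from the platform's annotation, with symbols updated by Entrez identifier in the RefSeq table of GRCm38.p6, which held 21994 of 22180 named genes. There were 23521 probe sets with 1 gene symbol, 1814 with several and 16010 with none listed. For the 1082 genes with more than 1 probe set the one with the highest mean over the 6 arrays was kept. Genes with a mean at or above the 30th percentile of named genes, 4.13, were tested, 15526 in all. Coordinates are not given because the annotation's build is not named.

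Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior, no covariate), with Benjamini-Hochberg adjustment over tested genes. Differences are Chd7f/f minus control. Counts are at an adjusted p under 0.05, and also at an unadjusted p under 0.05 with a fold of at least 1.5, which is not corrected for multiple tests. Gene lists were tested with camera at a preset correlation of 0.01 on lists with at least 5 tested members, adjusted over lists. They were repeated with an estimated correlation, with ranks and with fry. The 44 lists hold 1082 different genes, of which 952 were measured by a probe set of a single gene and 868 were tested. Chd7 is in no list, and some genes are in several lists. Mouse Reactome pathways came with fgsea 1.28.0 and were tested the same way when they held 10 to 300 tested genes. Plots were drawn with matplotlib.

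Chd7 was named whatever its value. The 15 genes with the largest higher and lower values were to be taken from those past the adjusted threshold with no overlap between genotypes, and, where these ran short, from genes with an unadjusted p under 0.05, a fold of at least 1.5 and no overlap. None passed the adjusted threshold, so all 30 come from the second source, and their size and lack of overlap are a matter of selection. Predicted genes, snoRNAs and microRNAs were not named. From each list described, up to 4 members with the smallest p were named. Kit, Runx1, Cbfb and Ciita were added after their values were seen. These rules, the tests of genes, lists and pathways, the lists themselves and all alternatives but 1 were fixed before the data were examined. The rules for reading fits as tests of an explanation, and the tests made for that alone, were set after the results were seen.

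The steps were checked on simulated data for this comparison, with 3 against 3 arrays and 15526 genes, spread drawn from the fitted prior and 200 genes changed in each of 5 data sets. Limma recovered 34.0% of genes changed by a log2 value of 1, 83.6% at 2 and 93.3% at 3, with 36 false calls over all sets. Of unchanged genes 4.85% had an unadjusted p under 0.05. Camera found 15 of 15 lists shifted by a log2 value of 1 and called 1 of 140 lists that shared no member with them. Simulated genes vary independently, so the check does not cover correlated members.

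Alternatives were another quantile normalization, median centring, no filter and a filter at the 50th percentile, the mean of a gene's probe sets, every probe set on its own, a trended and robust prior, array weights, the replicate number as a block, an adjusted p under 0.1, an unadjusted p under 0.01 with a fold of 2, and leaving out each array in turn. A fit without both arrays numbered 1 was added after the data were seen. No batch, date or cage is given in the labels used here. The sex of the mice is not in the labels either, and a fit with sex as a term was not made because 1 array alone has the female pattern.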

Results

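The series compares leukemic cells of 2 mouse genotypes, and asks what the loss of Chd7, a chromatin remodelling ATPase, changes in the transcriptome of a core-binding factor leukemia. Both genotypes carry Mx1-Cre, a recombinase induced by the interferon response to pIpC, and Cbfb+/56M, a conditional allele of the Cbfb-MYH11 fusion gene of inv(16) acute myeloid leukemia. In 1 genotype Chd7 is also floxed on both alleles (Chd7f/f); the other is called the control here. All mice received pIpC and the mutagen ENU, and cells carrying the stem cell factor receptor c-Kit were sorted from the spleen once leukemia had reached its end stage. RNA of 3 independent samples per genotype, called leukemias here, was hybridised to whole-transcript expression arrays, 1 array per sample. Values are RMA levels on the log2 scale, differences are Chd7f/f minus control, and the number of arrays limits the precision of every value.

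Kit, the gene behind the sort, was at 11.84 ± 0.24 (SD, n = 3) in the control and at 12.03 ± 0.41 (SD, n = 3) in Chd7f/f leukemias. Runx1, the DNA-binding partner of Cbfb, was at 11.73 ± 0.36 in the control and 11.71 ± 0.14 in Chd7f/f leukemias, and Cbfb itself at 9.48 ± 0.061 and 9.69 ± 0.29 (SD, n = 3 each). None of the 3 genes passed the test (limma, adjusted p = 0.9998 for each).

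Individual leukemias differed from each other more than the genotypes did. The first principal component held 33.7% of the variance and set control replicate 1 apart, at a score of -55.0. The second component held 30.2% and had Chd7f/f replicate 1 at -45.2 and Chd7f/f replicate 2 at 33.2, the lowest and the highest of the 6 arrays. Pearson correlations between arrays, taken across genes, which are not independent replicates, ran from 0.968 to 0.986. Their mean was 0.976 within and 0.977 between genotypes. Genotype accounted for 16.3% of the variance, where 20% is the share that a grouping without any difference gives on average.

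**Figure D1:**
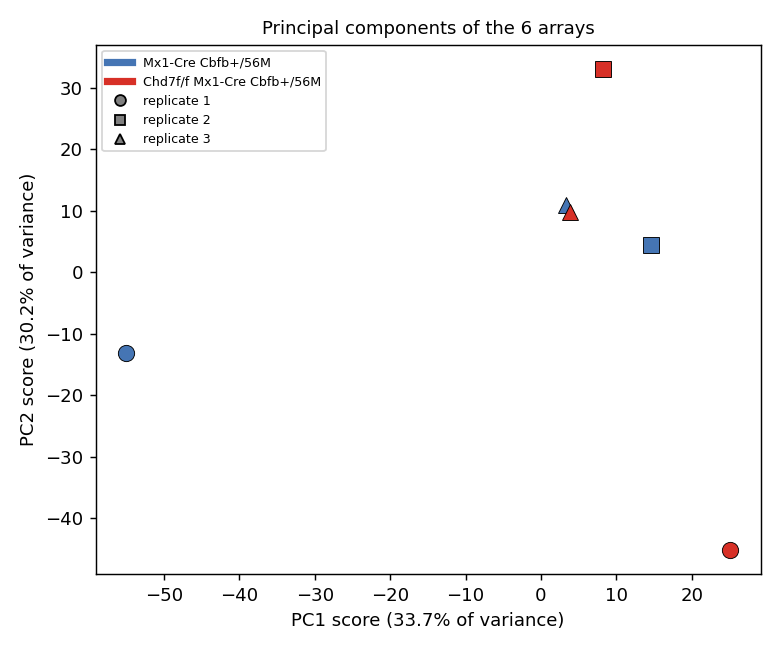
Scores of the 6 arrays on the first (x axis) and second (y axis) principal component of the tested genes, with colour for genotype and marker shape for replicate number. Control replicate 1 lies at -55.0 on the first component, Chd7f/f replicate 1 at -45.2 on the second, and the genotypes do not separate.

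The sex-linked genes differed on 1 array. Xist, transcribed from the inactive X chromosome, was at 10.1 in control replicate 2 and between 3.30 and 3.88 on the other 5 arrays. The Y-linked gene Eif2s3y was at 4.43 in control replicate 2 and between 8.72 and 9.11 elsewhere. Control replicate 2 therefore has the female pattern of these genes and the other 5 arrays the male pattern.

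Chd7, the targeted gene, was at 6.17, 7.54 and 5.32 on the 3 control arrays, a mean of 6.34 ± 1.12 (SD, n = 3). On the Chd7f/f arrays it was at 5.48, 6.50 and 5.91, a mean of 5.96 ± 0.51 (SD, n = 3). The difference of -0.38 (SE 0.58) lay within the spread between leukemias of either genotype (limma, adjusted p = 0.9998). It was 0.22 without control replicate 2, the array with the highest level, and -0.89 without control replicate 3. Without Chd7f/f replicate 2 it was -0.65, and with array weights -0.075. The probe set gives 1 value for the whole gene. The part that Cre removes and the places of the probes are not given in the sources used here, so this level does not check the deletion.

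The 15 genes named for the largest higher values in Chd7f/f leukemias differed by 1.03 to 1.78. P3h2, a collagen prolyl 3-hydroxylase, was 1.78 higher (SE 0.60), at 9.60 ± 0.33 against 7.82 ± 1.23 (SD, n = 3 each). P2rx7, an ATP-gated ion channel of leukocytes, was 1.61 higher (SE 0.58), and Hrh4, a histamine receptor, 1.32 higher (SE 0.30). Fcgr2b, the inhibitory Fc gamma receptor, was 1.26 higher, and the MHC class II chain genes H2-Ab1 and H2-Aa were 1.23 and 1.08 higher. Mpeg1, which encodes the macrophage pore-forming protein perforin-2, was 1.12 higher, and Pld4, a lysosomal exonuclease gene, 1.32 higher. The deubiquitinase gene Otud1 was 1.43 higher (SE 0.31) and the gamma-secretase activator Gsap 1.49 higher (SE 0.39). The remaining genes named on this side were Mctp1 (1.29), S100a6 (1.18), Srpk2 (1.12), Ltbp4 (1.09), which binds latent TGF-beta, and Cited4 (1.03), a transcriptional coactivator. The 3 values of each of these 15 genes lay above the 3 control values, and none passed the adjusted threshold (limma, adjusted p = 0.9998). Without control replicate 1 Fcgr2b was 0.66, Srpk2 0.68 and Cited4 0.54 higher, without Chd7f/f replicate 1 P2rx7 was 1.01, without Chd7f/f replicate 2 S100a6 was 0.73 and without Chd7f/f replicate 3 Pld4 was 0.87 higher. Array weights brought P3h2 to 1.15 and Srpk2 to 0.74, and without both arrays numbered 1, a fit added after the data were seen, P3h2 was at 1.17, Fcgr2b at 0.83, Srpk2 at 0.54 and Cited4 at 0.50.

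On the lower side the differences were larger. Gzmb, which encodes the cytotoxic granule protease granzyme B, was at 5.68 ± 1.64 in Chd7f/f and 8.75 ± 1.11 in control leukemias (SD, n = 3 each), a difference of -3.07 (SE 0.92). Dtx4, a deltex ubiquitin ligase gene of the Notch pathway, differed by -2.85 (SE 0.79), from 9.89 ± 1.29 in the control to 7.04 ± 1.11 (SD, n = 3 each). The palmitoyltransferase gene Zdhhc2 differed by -2.33 (SE 0.73), the Golgi GTPase gene Rab6b by -2.02 (SE 0.59) and the oxysterol-binding protein gene Osbpl3 by -1.99 (SE 0.41). Aco1, the cytosolic aconitase that doubles as iron regulatory protein, differed by -1.94 (SE 0.34), from 8.16 ± 0.37 to 6.22 ± 0.59 (SD, n = 3 each). Creb3l2, a membrane-bound bZIP transcription factor, differed by -1.61 (SE 0.27), with the smallest unadjusted limma p of the named genes at 0.000802. The others were Parm1 (-1.85), Tshz3 (-1.72), Plcb1 (-1.70), Proser2 (-1.66), Ndrg2 (-1.59), Ggact (-1.56), Rragb (-1.49), a Rag GTPase of amino acid signalling, and Atrnl1 (-1.48). All 15 genes had their 3 Chd7f/f values below the 3 control values, and none passed the adjusted threshold (limma, adjusted p = 0.9998). Proser2 was at -0.85 without control replicate 1 and -0.89 without both arrays numbered 1, Atrnl1 at -0.88 without control replicate 3 and Ndrg2 at -0.94 without Chd7f/f replicate 2; array weights brought Gzmb to -1.94 and Plcb1 to -1.05, and the mean of its probe sets Rab6b to -1.09.

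**Figure D2:**
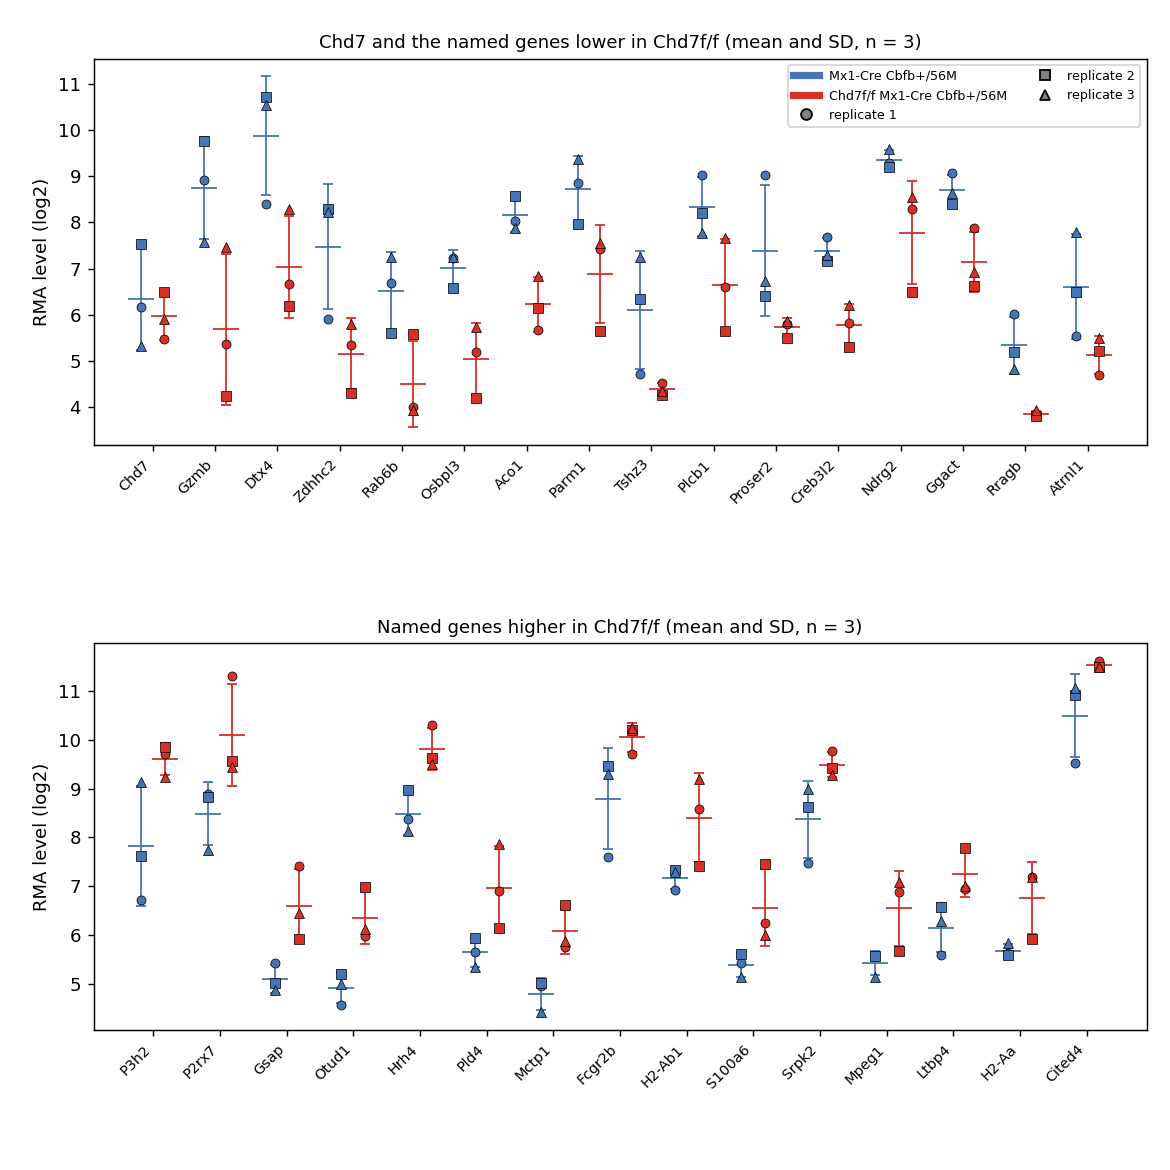
RMA levels (y axis, log2) of Chd7 and the 30 named genes on each array, with points for leukemias, horizontal ticks for the mean and bars for the SD of the 3 arrays of a genotype. The Chd7 values of the genotypes overlap, with means of 6.34 and 5.96, while those of the other genes, which were chosen for this, do not.

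No gene passed an adjusted p of 0.05 among the 15526 tested. The limma count at an unadjusted p under 0.05 was 286, or 1.84% of the genes where 5% is the share without any difference. With a trended, robust prior the unadjusted count was 345 and with array weights 571, and again 0 genes passed after adjustment. Values of the 3 arrays of each genotype did not overlap for 1058 genes, 6.81% of those tested, where chance gives 10%. At an unadjusted p under 0.05 together with a fold of at least 1.5, 121 genes remained, 54 higher and 67 lower in Chd7f/f leukemias. That count was 283 without control replicate 2, 202 without control replicate 3 and 183 without Chd7f/f replicate 3. An exact two-sided permutation test of 3 against 3 arrays cannot give a p below 0.1.

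Of the 44 gene lists fixed before the data were examined, 43 could be tested and 7 passed an adjusted p of 0.05 in limma's camera test with a preset correlation, 5 higher and 2 lower in Chd7f/f leukemias. With an estimated correlation between members, 0 of the 43 lists passed at adjusted or unadjusted p under 0.05, and fry, which asks whether a list moves one way on balance, gave 0 lists at an adjusted p under 0.05. Leaving out control replicate 3 brought the camera count to 4, control replicate 2 to 11 and Chd7f/f replicate 2 to 14.

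Monocyte and macrophage genes rose as a list in Chd7f/f leukemias (camera, adjusted p = 1.67e-06, median 0.36; adjusted p = 0.909 with an estimated correlation). Of 27 tested members 24 were higher and 3 lower. Mpeg1 was 1.12 higher, the lysosomal protease gene Ctss 1.08, the membrane protein gene Ms4a6c 0.96 and the MD-1 gene Ly86 0.95 higher. Ms4a6c was at 7.05 in Chd7f/f replicate 3 and at most 5.57 on the other arrays, where it may lie near background. No member passed alone over all genes or adjusted over the list alone (limma), and 1 had an unadjusted p under 0.05. The mean of the list relative to its average over the arrays was 0.31, -0.28 and 0.61 on the Chd7f/f arrays and -0.097, 0.17 and -0.72 on the control arrays. Without control replicate 3 the mean difference went from 0.43 to 0.18 (adjusted p = 0.0650); it was 0.23 without Chd7f/f replicate 3, 0.67 without Chd7f/f replicate 2 and 0.73 with array weights. Ctss was 0.63 and Ly86 0.58 higher without control replicate 3, and Ms4a6c 0.44 and Ly86 0.61 higher without Chd7f/f replicate 3; array weights brought Ms4a6c to 1.49.

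MHC class II genes also rose as a list (camera, adjusted p = 0.000226, median 0.55; adjusted p = 0.909 with an estimated correlation). Of 7 tested members 6 were higher and 1, the transactivator gene Ciita, lower at -0.053, or 0.041 higher without Chd7f/f replicate 2. H2-Ab1 was at 8.40 ± 0.91 in Chd7f/f and 7.17 ± 0.23 in control leukemias, and H2-Aa at 6.77 ± 0.74 and 5.68 ± 0.13 (SD, n = 3 each). H2-Eb1 was 0.55 higher and H2-DMa 0.32 higher. The higher values came from Chd7f/f replicates 1 and 3, with list means of 0.55 and 0.65, while Chd7f/f replicate 2 was at -0.32. No member passed over all genes or adjusted over the list alone (limma), and 2 had an unadjusted p under 0.05. The call held without each array in turn, with mean differences from 0.41 to 0.89, the latter without Chd7f/f replicate 2, against 0.59 with all arrays. It was lost without both arrays numbered 1 (0.33, adjusted p = 0.290), and H2-Eb1 and H2-DMa were 0.35 and 0.17 higher without Chd7f/f replicate 3 and 0.82 and 0.50 higher without Chd7f/f replicate 2.

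Neutrophil maturation genes rose with them (camera, adjusted p = 0.000346, median 0.20; adjusted p = 0.909 with an estimated correlation), with 16 members higher and 2 lower of 18. Cybb, the heme subunit of the phagocyte oxidase, was 1.13 higher, the integrin gene Itgam 0.83, Anxa1 0.63 and Ly6g 0.30 higher. Control and Chd7f/f means were 4.78 and 5.61 for Itgam, 4.95 and 5.58 for Anxa1 and 4.08 and 4.38 for Ly6g. All lay under 5.78, the level 1 log2 above the median level of the arrays, so these genes may lie near background. No member passed over all genes or adjusted over the list alone (limma), and 1 had an unadjusted p under 0.05. Chd7f/f replicate 3 carried this list, at 0.77 against -0.051 and -0.24 on the other Chd7f/f arrays. Without that array the mean difference went from 0.32 to 0.014 (adjusted p = 0.654), and it was 0.52 without Chd7f/f replicate 2 and 0.63 with array weights. Itgam was 0.38 higher without Chd7f/f replicate 3 and 1.28 higher with array weights.

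DNA replication and mitosis genes fell as lists in Chd7f/f leukemias. Of the 40 tested genes of DNA replication and the G1/S transition 38 were lower and 2 higher (camera, adjusted p = 0.000104, median -0.53; adjusted p = 0.909 with an estimated correlation). All 45 tested genes of G2/M and mitosis were lower (camera, adjusted p = 0.00653, median -0.44; adjusted p = 0.909 with an estimated correlation). Ccne1, the cyclin of S phase entry, differed by -0.66, Dtl by -0.75, the helicase gene Mcm4 by -0.61 and E2f8 by -0.54. In mitosis, the spindle checkpoint kinase gene Bub1 differed by -0.76, the kinesin gene Kif20a by -0.60, the condensin gene Ncapd2 by -0.53 and the cyclin gene Ccnb2 by -0.49. No member of either list passed over all genes, adjusted over the list alone (limma) or at an unadjusted p under 0.05. Chd7f/f replicate 1 carried both lists, at -1.29 for replication and -1.43 for mitosis, while Chd7f/f replicates 2 and 3 were at 0.34 and 0.23 for replication and at 0.53 and 0.33 for mitosis. Without Chd7f/f replicate 1 the replication list was 0.046 higher in Chd7f/f leukemias (camera, adjusted p = 0.533). The mitosis list was then 0.24 higher (camera at the preset correlation, adjusted p = 5.95e-08). That p takes members as nearly independent, while their estimated correlation over all arrays was 0.92. The mitosis list also lost its call without control replicate 1 (-0.31, camera, adjusted p = 0.0717) or control replicate 3 (-0.27, camera, adjusted p = 0.399). Without Chd7f/f replicate 2 the mean differences were -0.77 for replication and -0.74 for mitosis, without Chd7f/f replicate 3 -0.71 and -0.64, and without control replicate 1 replication was at -0.31. Both calls were lost with array weights, at -0.13 (adjusted p = 0.361) and -0.044 (adjusted p = 0.865), and both lists were higher without both arrays numbered 1, by 0.22 and 0.31. Without Chd7f/f replicate 1 Ccne1 was at -0.14, E2f8 at -0.26, Dtl at -0.20 and Mcm4 at -0.043, while Ccnb2, Kif20a, Bub1 and Ncapd2 turned to 0.075, 0.14, 0.20 and 0.17; without control replicate 1 E2f8 was at -0.25, Dtl at -0.43 and Mcm4 at -0.37. Erythroid genes had list means of 0.79 in control replicate 1 and -0.70 in Chd7f/f replicate 1, where the replication list was at 0.58 and -1.29. Whether the erythroid signal came from the leukemic cells or from other cells was not tested.

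**Figure D3:**
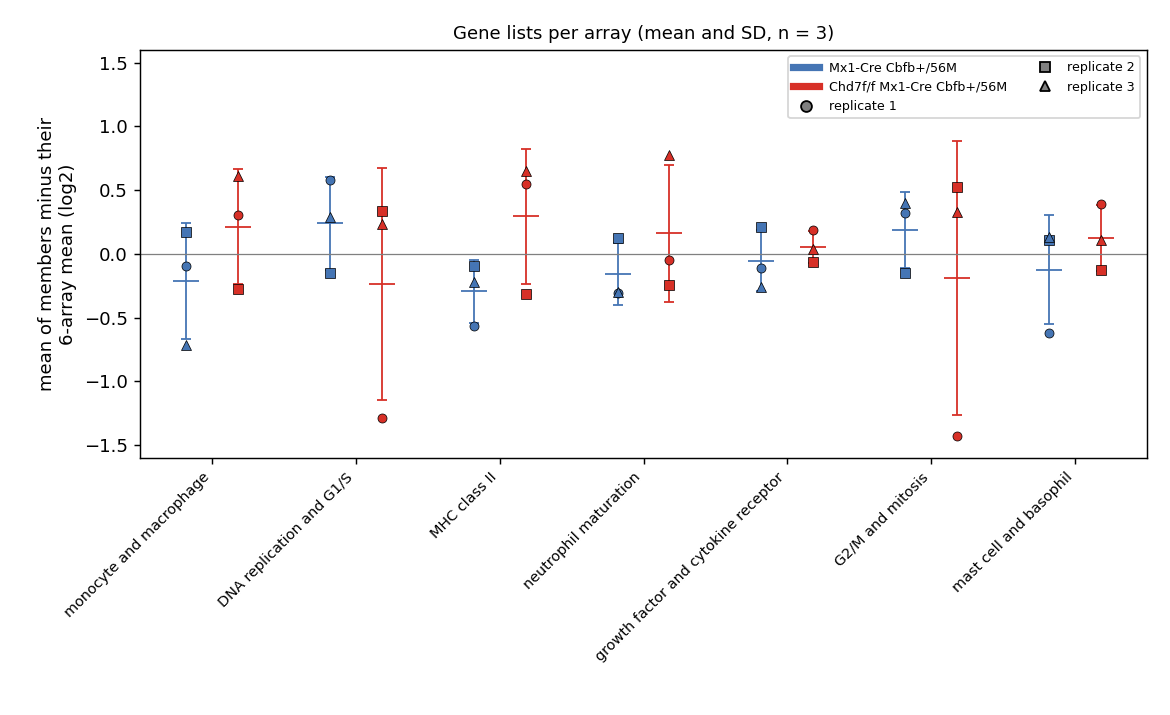
Mean level of the members of the 7 called gene lists on each array, relative to their average over the 6 arrays (y axis, log2), with points for leukemias, horizontal ticks for the mean and bars for the SD of the 3 arrays of a genotype. Chd7f/f replicate 1 lies at -1.29 for the replication list and -1.43 for the mitosis list, and the genotypes overlap in all 7 lists.

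Growth factor and cytokine receptor genes rose as a list (camera, adjusted p = 0.00641, median 0.16; adjusted p = 0.909 with an estimated correlation), with 18 of 24 members higher. Il6ra was 0.40, Tnfrsf1b 0.46 and Csf1r, the receptor of macrophage colony-stimulating factor, 0.78 higher, while the chemokine receptor gene Cxcr4 differed by -1.69. Mast cell and basophil genes rose too (camera, adjusted p = 0.0336, median 0.076; adjusted p = 0.909 with an estimated correlation), with 8 of 12 members higher. Among them Cd200r3 was 0.88, the histidine decarboxylase gene Hdc 0.86, Il4 0.82 and the Fc epsilon receptor gene Ms4a2 0.40 higher. No member of either list passed over all genes, adjusted over the list alone (limma) or at an unadjusted p under 0.05. The receptor list had a mean difference of 0.11 and lost its call without control replicate 1 (0.082), control replicate 3 (0.0041) or Chd7f/f replicate 1 (0.043), with adjusted p of 0.146, 0.203 and 0.210; without control replicate 2 it was 0.24 and without Chd7f/f replicate 2 0.17, and without both arrays numbered 1 0.016 (adjusted p = 0.981). Cxcr4 was at -0.75 without control replicate 1, -2.67 without Chd7f/f replicate 1 and -0.92 without Chd7f/f replicate 2, Csf1r 0.38 and Il6ra 0.26 higher without Chd7f/f replicate 3, Csf1r 0.51 and Tnfrsf1b 0.24 higher without control replicate 3, and Csf1r 1.30 higher with array weights. The mast cell list, at 0.25, lost its call without control replicate 1 (0.0051), Chd7f/f replicate 1 (0.12) or Chd7f/f replicate 3 (0.26), with adjusted p of 0.297, 0.624 and 0.0568; without control replicate 3 it was 0.38. Its call was also lost with array weights (0.096, camera, adjusted p = 0.512) and with another quantile normalization (0.26, camera, adjusted p = 0.0520). With the replicate number as a block the call was lost as well (0.25, camera, adjusted p = 0.0501). The mean difference of the list turned to -0.13 without both arrays numbered 1 (camera, adjusted p = 0.826). Without control replicate 1 Il4 was 0.35, Cd200r3 0.35, Hdc 0.26 and Ms4a2 0.077 higher, and without control replicate 2 Cd200r3 was 1.32 and Hdc 1.36 higher.

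The other 36 tested lists did not pass, with adjusted p from 0.0554 to 0.929. Cholesterol synthesis genes and MYC target and nucleolar genes were nearest, both at an adjusted p of 0.0554 (camera). They had 14 of 17 and 32 of 39 members lower. Of the 4 cholesterol synthesis genes with the smallest p, Stard4 was 0.51 higher, while Lss was at -0.35, Hsd17b7 at -0.85 and Insig1 at -0.35. The list means were lowest in Chd7f/f replicate 1, at -0.48 for cholesterol synthesis and -0.60 for MYC targets. Chd7f/f replicates 2 and 3 were at 0.037 and 0.12 for cholesterol synthesis and at 0.28 and 0.059 for MYC targets. The control arrays lay between 0.0698 and 0.15 and between 0.018 and 0.17. Azurophil granule genes had 10 of 13 members higher (camera, adjusted p = 0.0831), with Hp 0.68 and Serpinb1a 0.83 higher. Cst7 went the other way at -0.41, and was lowest in Chd7f/f replicate 2 at 9.86. Without control replicate 1 Serpinb1a was 0.17 and without Chd7f/f replicate 3 Hp was 0.26 higher. Array weights gave 0.48 for Serpinb1a and 1.12 for Hp. Erythroid genes had 16 of 21 members lower (adjusted p = 0.125), with Epb42 at -1.32 and Cpox at -0.92, and their list mean was 0.79 in control replicate 1 and -0.70 in Chd7f/f replicate 1. Without control replicate 1 Epb42 was at -0.56 and Cpox at -0.60, without Chd7f/f replicate 1 they were at -0.88 and -0.48, and array weights gave -0.72 and -0.48. No member of these lists passed adjusted over the list alone (limma); at an unadjusted p under 0.05 there was 1 cholesterol synthesis gene, Lss, at -0.35, and no gene of the other 3 lists.

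Lists tied to the core-binding factor did not pass either. RUNX1 target genes had 14 of 22 members higher (adjusted p = 0.147), with Csf1r 0.78, Runx3 0.55 and Cebpa 0.25 higher and Socs3 at -0.42; leaving out Chd7f/f replicate 2 brought this list to an adjusted p of 0.0287. Runx3 was 0.30 higher without control replicate 1 and 0.16 higher with array weights, and Socs3 was at -0.096 without control replicate 2 and -0.65 without control replicate 1. Genes linked to Cbfb-MYH11 and inv(16) leukemia had 10 of 16 members lower (camera, adjusted p = 0.478). The caveolae gene Cavin1 was at -0.78, Plag1 at -0.55 and Nt5e at -0.35, while Bmi1 was 0.22 higher. Plag1 was at -0.22 without control replicate 1, -0.89 without control replicate 3 and -0.31 with array weights. Nt5e was at -0.16 without control replicate 2. Other CHD and SWI/SNF remodeller genes had 15 of 28 lower (adjusted p = 0.829), with Smarca4 at -0.37, or -0.19 without Chd7f/f replicate 1, and Chd3 0.34 higher, or 0.16 without control replicate 1. Stem cell genes had 18 of 30 lower (camera, adjusted p = 0.666), with Ctnnal1 at -0.82. Of p53 target genes 16 of 28 were lower (camera, adjusted p = 0.680). Of the 4 members with the smallest p, Tnfrsf10b was at -0.69 and Pmaip1 at -0.91, while Bbc3 was 0.25 and Trp73 0.21 higher. Tnfrsf10b was at 5.73 in control replicate 2 and at 4.32 and 4.62 on the other control arrays. Pmaip1 was at -0.33 without control replicate 1 and -0.44 with array weights. Notch target genes had 11 of 14 members lower (camera, adjusted p = 0.206). Among them Dtx4 differed by -2.85, Notch3 by -0.17, Hey2 by -1.03 and Il2ra by -0.85. Without control replicate 1 Hey2 was at -0.14 and Il2ra at -1.29, with array weights Hey2 was at -0.57, and Il2ra was at -1.36 without control replicate 3 and turned to 0.11 without control replicate 2. No member of these 6 lists passed adjusted over the list alone (limma), and 1 gene each of the Cbfb-MYH11, stem cell and Notch lists had an unadjusted p under 0.05.

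Markers of other cells that a sort of spleen can hold gave no passing list beyond those above. T and NK cell genes had 10 of 17 members lower (adjusted p = 0.483, median -0.018), and after Gzmb the chemokine gene Ccl5 at -0.86 and Thy1 at -1.25 led the list. Without control replicate 1 Ccl5 was at -0.55 and Thy1 at -0.70, without Chd7f/f replicate 2 Thy1 was at -0.72, and with array weights Ccl5 was at -0.55. B cell genes had 7 of 13 members higher (adjusted p = 0.829), with a median of 0.0044 and a mean of -0.068. Stromal and endothelial genes had 11 of 18 lower (adjusted p = 0.675), with a median of -0.082 and a mean of 0.032. Dendritic cell genes were 4 higher and 4 lower (adjusted p = 0.576), megakaryocyte genes 9 higher and 7 lower (adjusted p = 0.574), and eosinophil genes 3 higher and 3 lower (adjusted p = 0.573). No member of these 6 lists passed adjusted over the list alone (limma), and 2 T and NK cell genes, Gzmb and Ccl5, had an unadjusted p under 0.05.

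Among 815 Reactome pathways, 6 passed, all lower in Chd7f/f leukemias at an adjusted p of 0.0471 (camera; adjusted p = 0.982 with an estimated correlation, where 0 passed). They were DNA replication (median -0.19), its pre-initiation step, the transition from mitosis to G1, DNA synthesis, the G1 to G1/S phases and activation of the pre-replicative complex (median -0.38), with 29 to 111 genes each. The pre-initiation and mitosis to G1 pathways gave identical values (72 genes each, median -0.18, camera, unadjusted p = 0.000238), so they are not separate results. The number of pathways was 0 without control replicate 1 or control replicate 3. It was 33 without Chd7f/f replicate 1, 78 without control replicate 2, 105 without Chd7f/f replicate 3 and 195 without Chd7f/f replicate 2. These counts hold pathways of either direction. Without Chd7f/f replicate 1 the replication list was 0.046 higher and the mitosis list 0.24 higher. The 33 pathways therefore cannot be read as the same 6 lower pathways.

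Probe sets without a gene or with several genes were tested apart. Of 17824 such probe sets 10087 were at or above the level filter. In limma 0 passed an adjusted p of 0.05, and 289 had an unadjusted p under 0.05.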

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

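The fit without both arrays numbered 1 was chosen after the data were seen; the other alternatives were planned. Limma gave 0 genes past an adjusted p of 0.05 or 0.1 under each alternative, with a smallest adjusted p of 0.192, without control replicate 1. Its unadjusted count of 286 was 270 to 477 without 1 array, 159 to 571 over all alternatives on genes and 1207 over every probe set. The difference of Chd7 was -0.89 to 0.22 without 1 array, turning without control replicate 2, the array with its highest level. The 30 named genes were chosen for values that do not overlap, which fixes their direction without 1 array; 9 of them and 37 of 47 list members checked moved by over 1.5 times without 1 array. The count past unadjusted p and fold, 121, was 128 to 283 without 1 array, 186 with array weights, 407 over every probe set, where more features are tested, and 16 at p under 0.01 and 2-fold, a stricter threshold. The 7 lists became 4 to 14 without 1 array, 11 with median centring, 11 without both arrays numbered 1, and 0 with an estimated correlation or with fry, which allow for members that vary together. The 6 Reactome pathways became 0 to 195 without 1 array, 41 with median centring, 10 without the filter, 45 with the filter at the 50th percentile, 76 without both arrays numbered 1, and 0 with the mean of a gene's probe sets, the trended prior, array weights or an estimated correlation; the cause was not tested. List and pathway counts include both directions. No detection call tells which tested genes, those at a mean of 4.13 or more, lie over background. Centring moved the median of all tested genes from -0.027 to 0.025. Without 1 array the replication list was at -0.77 to 0.046 and the mitosis list at -0.74 to 0.24, Ccnb2 at -0.78 to 0.075, Kif20a at -1.002 to 0.14, Bub1 at -1.33 to 0.20 and Ncapd2 at -0.91 to 0.17; each turned without Chd7f/f replicate 1. Il2ra, at -1.36 to 0.11, turned without control replicate 2. Without both arrays numbered 1 the replication list was at 0.22, the mitosis list at 0.31, the mast cell list at -0.13, and the MHC class II list at 0.33 and the receptor list at 0.016 without their calls, with E2f8 at 0.039, Dtl at 0.12, Mcm4 at 0.19, Ccnb2 at 0.086, Kif20a at 0.15, Bub1 at 0.20 and Ncapd2 at 0.23. Array weights were lowest for Chd7f/f replicate 1, at 0.418, and control replicate 1, at 0.609, and with them the replication list was at -0.13, the mitosis list at -0.044 and the mast cell list at 0.096, each without its call, while the monocyte list was at 0.73 and the neutrophil list at 0.63. Over the 7 called lists and the RUNX1 target list, 107 alternative values kept direction and side of the threshold, 31 lost and 1 gained the call, and 5 turned.

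Replicate numbers do not pair the arrays: deviations of arrays with the same number correlated at 0.027, -0.025 and 0.034 across genes. With the number as a replicate block, 0 genes passed, 332 had an unadjusted p under 0.05, 171 passed unadjusted p and fold, 7 lists passed, and 0 Reactome pathways passed. The mast cell list then lost its call (camera, adjusted p = 0.0501), so these 7 lists were not the same as in the main fit. Control replicates 1, 2 and 3 each correlated best with Chd7f/f replicate 3 (0.976, 0.984 and 0.986). For control replicate 3 that is the array of its own number, so these correlations do not bear on pairing.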

Other observations

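Some list members apart from the lists described stood out. The ribosomal protein gene Rpl3 was 0.76 higher (SE 0.15) in Chd7f/f leukemias, at 11.5 to 11.8 against 10.7 to 11.1 on the control arrays, but 0.11 higher with the mean of its probe sets, while 29 of the 57 tested ribosomal protein genes were lower and the list did not pass (camera, adjusted p = 0.411). Xrcc5, which encodes the Ku80 subunit of the end-joining machinery, differed by -0.96 (SE 0.21), and 25 of 33 DNA repair genes were lower (camera, adjusted p = 0.116). The DNA repair list means were -0.49, 0.17 and 0.043 on the Chd7f/f arrays and 0.34, -0.20 and 0.13 on the control arrays. The kinase gene Pim1, a JAK-STAT target, differed by -0.34 (SE 0.10), at 11.04 to 11.08 against 11.35 to 11.47, in a list with 14 of 20 members lower (camera, adjusted p = 0.574). None of these genes passed the adjusted threshold of limma, and 1 ribosomal, 1 DNA repair and 1 JAK-STAT gene had an unadjusted p under 0.05.

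Single arrays stood apart from all others in many genes. The genes in this paragraph were picked after their values were seen. Control replicate 1 had 201 genes at least 2-fold above and 185 at least 2-fold below all other arrays. Among them the brain cadherin gene Pcdh10 was at 9.26 against at most 4.46, the lipase gene Lpl at 8.46 against at most 4.37, and Tek, the angiopoietin receptor, at 4.796 against at least 8.69. Chd7f/f replicate 1 had 71 genes above and 263 below all others in this way, with the ribonucleotide reductase gene Rrm2 at 7.001 against at least 9.36 and the stem cell growth factor gene Clec11a at 5.23 against at least 8.01. In Chd7f/f replicate 2 the metallothionein gene Mt2 was at 7.79 against at least 11.5 and the imprinted gene Mest at 7.59 against at most 5.25. Chd7f/f replicate 3 had the complement regulator gene Cd59a at 7.98 against at least 11.6 and the myeloid genes Lyz2 and F13a1 at 8.61 and 8.70 against at most 6.89 and 7.08. Control replicate 2, the array with the female pattern, had a mean of the interferon-induced list of 0.60 against at most 0.0080 elsewhere, with Rtp4 at 7.58 against at most 4.66.

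Leaving out each array, the estimated correlation and the splits of the arrays for genes past unadjusted p and fold were planned. The rules for reading these fits as tests of an explanation, and the other tests that follow, were set after the results were seen. Splitting the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. The genotype split gave 121 genes past unadjusted p and fold, 7 gene lists and 6 Reactome pathways. No other split gave a lower count of any of these, and the highest others were 354, 17 and 302. In limma 0 genes passed the adjusted threshold in each of the 10 splits, so that count does not set them apart. At an unadjusted p under 0.05 the count was 286 for genotype, the lowest of the 10 splits, and 968 for the highest other. The higher counts of genes at unadjusted p, of lists and of pathways point to a structure of the arrays that the genotypes do not follow.

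The lower replication and mitosis lists may come from a single leukemia, Chd7f/f replicate 1. Without it the mitosis list was 0.24 higher and the replication list 0.046 higher in Chd7f/f leukemias, so neither list stayed lower. A weaker signal of all bright probe sets on that array is argued against by the sizes. The 85 genes of both lists lay there at -1.63 from the mean of the other arrays. The 10000 random lists matched on mean level had a median of -0.13 and a lowest value of -0.40, so 0 were as low. That share is no p-value, because members of the replication and mitosis lists vary together (estimated correlations 0.77 and 0.92) while random genes need not. The array was also picked after it was seen to be lowest. Other lists lowest there included histone (-1.21), erythroid (-0.70), MYC target (-0.60), heat shock (-0.58), DNA repair (-0.49) and oxidative phosphorylation genes (-0.46). The erythroid list was highest in control replicate 1, at 0.79 with replication at 0.58. Chd7f/f replicates 2 and 3 were at 0.34 and 0.23 for replication and at 0.53 and 0.33 for mitosis, so the lowering was not shared by the Chd7f/f leukemias. Whether the cells of Chd7f/f replicate 1 cycled less was not tested, nor was any part of Chd7 in that leukemia.

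The MHC class II list had mean differences of 0.41 to 0.89 without 1 array, so no single array accounts for its direction. Its camera call at a preset correlation was kept without each array in turn, with a highest adjusted p of 0.0341. That call takes members as nearly independent, while their estimated correlation was 0.78, so it cannot argue against a single array. It was lost with the estimated correlation (camera, adjusted p = 0.909) and without both arrays numbered 1 (0.33, camera, adjusted p = 0.290). More B cells in the sort, which the c-Kit gate should remove, cannot be told apart from a change within the leukemic cells, because 4 of the 13 tested B cell genes had a mean at least 1 log2 above the median level of the arrays and the others lay nearer to the floor. These went both ways, with Ralgps2 0.49 higher, Cd37 at -0.54 (9.51 against 10.05), Ighm at -0.085 (10.94 against 11.03) and Jchain 0.0097 higher; without Chd7f/f replicate 2 the latter 3 were 0.083, 0.73 and 0.89 higher. On the Chd7f/f arrays the B cell list means of 0.28, -0.48 and 0.10 were lowest on replicate 2, as were the MHC class II means of 0.55, -0.32 and 0.65, and replicate 1 had the immunoglobulin genes Igkj1 at 10.8 against at most 7.67 and Igkv15-103 at 10.7 against at most 8.18.

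The higher monocyte list may rest on a single array, since it lost its call without control replicate 3 (adjusted p = 0.0650) and its mean difference went from 0.43 to 0.18. It also lost the call with an estimated correlation (adjusted p = 0.909). More macrophages, which the c-Kit gate should remove as well, cannot be told apart from a change within the leukemic cells. The macrophage complement genes C1qa, C1qb and C1qc differed by 0.20, 0.59 and 0.00028, a median of 0.20 against 0.36 for the list, within its spread of 0.43, and by -0.0077, 0.12 and -0.23 without control replicate 3; C1qb, the brightest, was at 8.09 against 7.50. The genotype stays open and untested as an explanation of this list and of the MHC class II list.

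Gzmb had the largest difference of the named genes, at -3.07, and was picked for its size among 15526 genes with no call behind it. It was at -3.96 to -2.35 without 1 array and at -1.94 with array weights. Of the other 16 tested T and NK cell genes, 4 had a mean at least 1 log2 above the median level of the arrays: Thy1 at -1.25, Ccl5 at -0.86, Nkg7 0.030 higher and Lat 0.10 higher. Thy1 was at -0.70 and Ccl5 at -0.55 without control replicate 1, and without 1 array Nkg7 was at -0.21 to 0.51 and Lat at -0.016 to 0.17. The others lay nearer to the floor, and no explanation of the lower Gzmb was tested.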
